A study of Mus musculus with 16 samples.

How the data were processed

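Expression was measured in hippocampal RNA of female mice perfused with PBS, in 16 libraries made with an oligo-dT SMARTer Ultra Low kit, per the labels' protocols. Bcl2fastq, STAR 2.5.1a and featureCounts 1.4.6-p5 of Subread on build GRCm38 are named in the submitters' processing notes, without roles. The deposited values are estimated counts per Ensembl gene (expected counts that need not be whole), and 74.53% of those above 0 were exactly whole as stored. The per-sample files deposited by the authors also hold TPM and an effective length per gene, in columns named as salmon writes them, per the file headers; the quantifier is not given in the sources used here. The series table had 55774 lines for 55487 genes, since 287 lines repeat a gene under another identifier, and each gene was kept once. All 887792 values compared equalled the per-sample files within 0.01 reads. Symbols were those of the deposited series table. Coordinates were taken from GENCODE M21 on GRCm38 by Ensembl identifier, which covered 55227 genes. The annotation behind the counts is not given in the sources used here.

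Groups and replicate numbers came from the labels. Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, quasi-likelihood F-tests with a mean per genotype over all 16 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. This tested 18565 genes in 5 contrasts: T against WT, CKO against WT, TCKO against T, TCKO against CKO and their interaction. The 25 gene lists, for microglia, astrocytes, interferon response, complement, cytokines, sterol metabolism, lysosome, matrix, neurons, immediate early genes, injury, oligodendrocyte lineage, vessels, choroid plexus, meninges, T cells, border macrophages, erythrocytes and neighbouring brain regions, were tested with camera in limma 3.58.1 on voom values with the preset correlation of 0.01, and again with an estimated correlation. Beside camera, fry asked whether a list's genes moved one way; it called 16, 0, 19, 6 and 9 lists in the 5 contrasts. Tnf, Il6, Sprr1a and Gzmb were removed by the filter. A list score is the mean log2 CPM of the members minus the WT mean, compared by exact two-sided permutation over 35 splits. The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

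That rule took Ch25h, Mapt and Prnp, the 8 largest rises and 8 largest falls past the threshold with at least 1 CPM in a group and no overlap between libraries, and up to 3 members of each list by p. It left out unnamed gene models, pseudogenes and ribosomal or mitochondrial genes. It gave 299 gene and comparison pairs, and the text prints a part of them as examples, picked after their values were seen. Some of the named genes are withheld and not reported here. Fold changes of genes with no reads in a group are given as lower bounds against a floor of 3 counts over the group, and with 1 to 3 reads as ratios with a 95% counting interval; both cover counting error only. This was not applied to the interaction, where fitted values are printed, and Ch25h in CKO against WT is printed both ways. A floor of 3 counts was between 0.0873 and 0.1991 CPM of the unscaled library total. Genes near Ch25h were compared with others by Fisher's exact test.

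Alternatives were DESeq2 1.42.0, limma voom, other normalizations, other filters on low counts, a fit of only the 8 compared libraries, a minimum fold, the replicate number as a block and leaving out each library. Thinning all libraries to 15064258 reads, an effective length offset, leaving out the choroid-rich libraries, leaving out mitochondrial genes and leaving Ch25h out of its own neighbourhood were added after seeing the data. Whether replicate numbers pair the libraries was checked from the correlation of same-numbered libraries around their group means. For WT and T all 3 pairs were over 0.1 (0.12 to 0.30), and so were all 3 of CKO and T (0.1 to 0.14), which are not compared directly but both enter the interaction; so the blocked values are given beside that comparison, and beside the interaction that contains it, where a call of a gene or list in the text changes. The rule was applied as written, but the blocked counts had been computed at the same time. On simulated data with known changes, the edgeR step recovered 23.9% of 1.5-fold, 61.2% of 2-fold and 89.4% of 4-fold changes for T against WT (18209 genes). For CKO against WT it recovered 19.4%, 68.7% and 98.5% (18207 genes), and for TCKO against T 28.4%, 53.7% and 92.4% (18223 genes). Mitochondrial genes took 9.19 ± 0.54% of reads in WT and 7.61 ± 0.74% in CKO (n = 4 each), and 7.01 to 9.79% over all libraries.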

Results

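Gene expression was measured by RNA sequencing in the right hippocampus of female mice aged 40 weeks, from a cross of PS19 mice with mice lacking Ch25h. PS19 mice carry a mutant human tau (MAPT) transgene under the prion protein promoter, and Ch25h encodes cholesterol 25-hydroxylase, the enzyme that makes the oxysterol 25-hydroxycholesterol. The 16 libraries form 4 groups of 4: wild type (WT), Ch25h knockout (CKO), tau transgenic (T) and tau transgenic with Ch25h knockout (TCKO). Library totals ran from 15064309 reads (CKO replicate 4) to 34348284 (WT replicate 2), with means ± SD of 30.81 ± 2.53 M reads in WT, 22.07 ± 4.9 in CKO, 30.51 ± 2.85 in T and 26.89 ± 3.13 in TCKO (n = 4 each). Fold changes are log2 values ± SE with n = 4 libraries per group unless stated, and levels are CPM, read counts relative to the library total scaled by its TMM factor, as mean ± SD. The labels number the replicates without saying that each library is a different mouse, so p-values measure the spread between these libraries.

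The targeted gene, Ch25h (ENSMUSG00000050370, GRCm38 chromosome 19, 34473778 to 34475164), was read 18, 25, 20 and 40 times in the WT libraries and 2, 0, 0 and 1 times in the CKO libraries. The T libraries held 300, 149, 154 and 133 Ch25h reads and the TCKO libraries 0, 1, 1 and 0. Every library therefore had the Ch25h level its label names. Ch25h rose in T against WT by 2.8 ± 0.42 (adjusted p = 0.000142), from 0.864 ± 0.373 CPM to 6.02 ± 2.41 CPM. The read ratio was 25.6 (95% counting interval 8.53 to 126) for WT against CKO and 323 (89.2 to 2680) for T against TCKO. Mapt (ENSMUSG00000018411, chromosome 11, 104231390 to 104332090) was at 347 ± 14.5 CPM in WT, 375 ± 10.7 CPM in CKO, 769 ± 96.2 CPM in T and 986 ± 141 CPM in TCKO. Prnp (ENSMUSG00000079037, chromosome 2, 131909928 to 131938429), the gene of the promoter that drives the transgene, rose by 1.17 ± 0.13 in T against WT and by 1.28 ± 0.13 in TCKO against CKO. Reads of the human transgene can be counted at the mouse gene where the sequences match, so the Mapt and Prnp values can mix both sources.

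**Figure D1:**
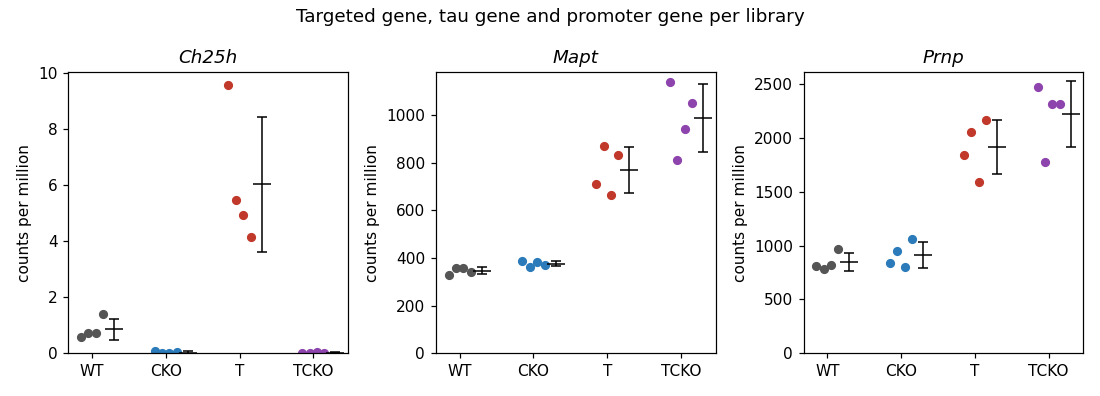
CPM of Ch25h, Mapt and Prnp (y axes) in each library (points) of the 4 groups (x axis), with the group mean and SD (black, n = 4). Ch25h averaged 6.02 CPM in T and 0.0172 in TCKO, while Mapt and Prnp were higher in all 8 transgenic libraries than in all 8 others.

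The comparison of T with WT asks what the tau transgene changes where Ch25h is intact. Microglial, interferon-stimulated, complement and reactive astrocyte genes rose together in T, while genes of cholesterol synthesis fell. C1qa, a subunit of the complement initiator C1q, rose by 3.71 ± 0.2, from 24.5 ± 5.29 CPM to 321 ± 70.6 CPM. Of 18565 genes tested, 4490 changed (2417 higher, 2073 lower), and 1388 of the rises and 187 of the falls were at least 2-fold. The falls were fewer in some fits: 1162 without T replicate 2, 1187 without T replicate 3, 1254 without a filter on low counts, 1380 from the 8 compared libraries alone and 882 without the choroid-rich libraries (WT replicate 1 and T replicate 4), where rises numbered 1772 to 2375. Of the 4490, 3667 had libraries that did not overlap between the groups. Over all genes 25.1% did not overlap, where chance gives 2.86%.

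Among disease-associated microglia genes, 22 of 24 rose, 0 fell and 2 did not pass (24 and 0 adjusted over the list alone), including Axl (1.77 ± 0.14), Tyrobp (2.93 ± 0.26) and Cd68 (3.19 ± 0.29). The disease-associated microglia list had a median log2 fold change of 2.67, with a camera adjusted p = 1.48e-23 and an adjusted p = 0.0413 with an estimated correlation. Itgax and Cst7, of the same list, rose by 8.18 ± 0.89 and 7.94 ± 0.88. Homeostatic microglia genes rose as well: 13 of 16 rose, 0 fell and 3 did not pass (13 and 0 adjusted over the list alone), with Csf1r (1.72 ± 0.15). The homeostatic microglia list had a median log2 fold change of 0.85, with a camera adjusted p = 9.68e-10 and an adjusted p = 0.0459 with an estimated correlation. All 21 interferon-stimulated genes rose, among them the antiviral genes Ifit2 (1.84 ± 0.18), Oas1a (3.77 ± 0.38) and Ifitm3 (3.03 ± 0.32). The interferon-stimulated list had a median log2 fold change of 3.03, with a camera adjusted p = 1.48e-23 and an adjusted p = 0.0455 with an estimated correlation. All 18 complement and antigen presentation genes rose, with C1qc at 3.36 ± 0.21 and C1qb at 3.03 ± 0.22. The complement and antigen presentation list had a median log2 fold change of 3.25, with a camera adjusted p = 3.34e-24 and an adjusted p = 0.0413 with an estimated correlation. The counts adjusted over the list alone were 21 and 18. Of cytokines and NF-kB targets, 12 of 16 rose, 0 fell and 4 did not pass (13 and 1 adjusted over the list alone), including the adhesion molecule Icam1 (3.29 ± 0.28) and the chemokine Ccl2 (5.51 ± 0.49). The cytokines and NF-kB targets list had a median log2 fold change of 1.93, with a camera adjusted p = 2.16e-09 and an adjusted p = 0.00995 with an estimated correlation.

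Of the reactive astrocyte list, 22 of 24 rose, 0 fell and 2 did not pass (24 and 0 adjusted over the list alone), with the transcription factor Stat3 (1.45 ± 0.14), the intermediate filament gene Vim (3.76 ± 0.36) and the guanylate-binding protein gene Gbp2 (3.23 ± 0.31). The reactive astrocytes list had a median log2 fold change of 2.8, with a camera adjusted p = 1.06e-19 and an adjusted p = 0.0413 with an estimated correlation. Astrocyte identity genes moved less, and 7 of 14 rose, 0 fell and 7 did not pass (8 and 1 adjusted over the list alone), including Sox9 (1.57 ± 0.17) and Aqp4 (1.8 ± 0.22). The astrocyte identity list had a median log2 fold change of 0.4, with a camera adjusted p = 0.000176 and an adjusted p = 0.204 with an estimated correlation. Of lysosomal genes, 13 of 14 rose, 0 fell and 1 did not pass (13 and 0 adjusted over the list alone), including Grn (1.74 ± 0.14) and Ctsz (2.54 ± 0.23). The lysosome list had a median log2 fold change of 1.06, with a camera adjusted p = 9.57e-13 and an adjusted p = 0.0455 with an estimated correlation. In the matrix list 8 of 16 rose, 1 fell and 7 did not pass (10 and 1 adjusted over the list alone), and the macrophage elastase Mmp12 (7.02 ± 0.76) rose. The matrix metalloproteinases and matrix list had a median log2 fold change of 0.82, with a camera adjusted p = 0.000558 and an adjusted p = 0.109 with an estimated correlation. T cell genes were higher too: 12 of 13 rose, 0 fell and 1 did not pass (12 and 0 adjusted over the list alone), with Cxcr6 (3.21 ± 0.56) and Cd3g (4.78 ± 0.87). The T cell list had a median log2 fold change of 3.13, with a camera adjusted p = 7.53e-08 and an adjusted p = 0.0457 with an estimated correlation. Cd3g stood at 1.97 ± 1.24 CPM in T.

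Cholesterol synthesis and uptake genes fell: 0 of 24 rose, 21 fell and 3 did not pass (0 and 23 adjusted over the list alone), including the pathway enzymes Msmo1 (-1.22 ± 0.15), Sc5d (-0.63 ± 0.08) and Idi1 (-1.05 ± 0.13). The cholesterol synthesis and uptake list had a median log2 fold change of -0.76, with a camera adjusted p = 9.04e-15 and an adjusted p = 0.0455 with an estimated correlation. Of LXR targets and sterol handling genes, 11 of 20 rose, 0 fell and 9 did not pass (14 and 1 adjusted over the list alone), with the cholesterol exporter Abca1 (2.44 ± 0.25), the lysosomal sterol carrier Npc2 (1.45 ± 0.14) and Clu (1.12 ± 0.11). The LXR targets and sterol handling list had a median log2 fold change of 0.64, with a camera adjusted p = 1.05e-06 and an adjusted p = 0.065 with an estimated correlation. Among excitatory neuron and synapse genes, 0 of 16 rose, 4 fell and 12 did not pass (0 and 6 adjusted over the list alone), including the glutamate receptor subunits Gria2 (-0.93 ± 0.15) and Gria1 (-0.65 ± 0.16) and synaptotagmin Syt1 (-0.43 ± 0.13). The excitatory neuron and synapse list had a median log2 fold change of -0.27, with a camera adjusted p = 0.00356 and an adjusted p = 0.326 with an estimated correlation. In the injury and stress response list 5 of 11 rose, 2 fell and 4 did not pass (5 and 2 adjusted over the list alone), with Nupr1 (2.12 ± 0.26) and Cdkn1a (2.21 ± 0.31) among the rises; the list was not called (median 0.00, adjusted p = 0.163). Where leaving out a single library ended a call, the adjusted p without it is given. Syt1 lost its call without WT 5 (0.0763) or T 2 (0.0667) or T 4 (0.0566).

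Markers of other cells moved beside these groups. Of oligodendrocyte and myelin genes, 7 of 14 rose, 0 fell and 7 did not pass (8 and 0 adjusted over the list alone), including Sox10 (1.32 ± 0.32) and Mag (1.36 ± 0.36). The oligodendrocyte and myelin list had a median log2 fold change of 0.96, with a camera adjusted p = 7.39e-05 and an adjusted p = 0.375 with an estimated correlation. The WT libraries spread widely in this list, with scores of -0.63, 0.75, 0.93 and -1.06. Lists not called were oligodendrocyte precursor (4 rose, 0 fell of 10, median 0.63, adjusted p = 0.0719), endothelium and pericyte (3 rose, 0 fell of 13, median 0.24, adjusted p = 0.0719), border macrophage and monocyte (4 rose, 0 fell of 12, median 0.76, adjusted p = 0.0569), hippocampal subfield neurons (0 rose, 2 fell of 16, median -0.36, adjusted p = 0.219) and inhibitory neuron (0 rose, 1 fell of 12, median -0.25, adjusted p = 0.212). Also not called were immediate early genes (2 rose, 1 fell of 14, median -0.05, adjusted p = 0.74), choroid plexus (0 rose, 0 fell of 15, median 0.07, adjusted p = 0.879), meninges and fibroblast (1 rose, 1 fell of 12, median -0.34, adjusted p = 0.417), erythrocyte (0 rose, 0 fell of 5, median -1.0, adjusted p = 0.2) and thalamus and striatum (2 rose, 1 fell of 12, median -0.32, adjusted p = 0.953). The choroid plexus score was 3.42 in WT replicate 1 and 3.57 in T replicate 4, and at most 0.59 in the other libraries. With the replicate number as a block, the border macrophage and monocyte list was called (adjusted p = 0.0257); in the fit without the block its adjusted p with an estimated correlation was 0.341. The block ended the calls of Junb (0.84 ± 0.28, blocked adjusted p = 0.143), Ier2 (0.84 ± 0.3, 0.113), Egr3 (-0.45 ± 0.16, 0.0732), Sox6 (0.55 ± 0.17, 0.127), Olig2 (1.05 ± 0.36, 0.108) and Drd1 (-0.85 ± 0.28, 0.0845). Single libraries decided these calls too. Junb lost its call without any one of WT 1, 2 or 5, T 2, 3 or 5 (0.0612 to 0.107). Ier2 lost its call without any one of WT 1, 2 or 5, CKO 2 or 5, T 2, 3 or 5, TCKO 2 or 5 (0.0512 to 0.139). Egr3 lost its call without any one of WT 2, 4 or 5, CKO 1, 2, 4 or 5, T 2, 3 or 4, TCKO 2, 3, 4 or 5 (0.0565 to 0.159). Sox6 lost its call without WT 2 (0.0835) or WT 4 (0.0851) or T 2 (0.101) or T 3 (0.0711). Olig2 lost its call without any one of WT 1, 2, 4 or 5, CKO 1 or 2, T 2 or 3 (0.0516 to 0.179). Drd1 lost its call without any one of WT 1, 2 or 5, CKO 4, T 2, 3 or 4, TCKO 4 (0.0514 to 0.0844). The border macrophage and monocyte list gained a call without WT 5 or T 2 or T 3 or T 5 (adjusted p from 0.0214 to 0.0473). The endothelium and pericyte list gained a call without WT 2 or WT 5 or T 5 (adjusted p from 0.0202 to 0.0478). The oligodendrocyte precursor list gained a call without WT 2 or WT 5 or T 4 or T 5 (adjusted p from 0.0268 to 0.0479).

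Genes read in T and not in WT were led by Gbp2b, an interferon-inducible GTPase gene, with 2286 reads in T and 0 in WT, at least 755-fold higher (floor of 3 counts over the group). Klrb1b, a lectin receptor gene, was at least 169-fold higher, with 511 reads against 0. Among falls, Sln (-3.58 ± 0.98) and Tph1 (-3.43 ± 0.67) were lower in T; the Sln call was lost without WT 2 (0.0668). Snurf, the named gene with the largest fitted fall, lies within Snrpn, and its value is uncertain because the division of reads between them was not tested. Without T replicate 2 the count of changed genes was 2934, and without the 2 choroid-rich libraries, WT replicate 1 and T replicate 4, it was 2696, an alternative chosen after seeing the data.

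The comparison of TCKO with T asks what loss of Ch25h changes in transgenic mice. Microglial, interferon-stimulated, complement and reactive astrocyte genes were lower in TCKO, and cholesterol synthesis genes were higher. The oligodendrocyte and myelin list, higher in T than in WT, did not pass here; its rise in T was not called with an estimated correlation (adjusted p = 0.375). Of 18565 genes, 2388 changed (893 higher, 1495 lower), with 924 of the falls and 58 of the rises at least 2-fold. The rises moved more between fits than the falls: 282 without T replicate 2, 463 without T 3, 516 without T 4, 1483 without T 5, 488 without TCKO 2 and 428 without TCKO 5, where falls numbered 1012 to 1795. Rises were 202 (1152 falls) from the 8 compared libraries alone, 477 (1455) without a filter on low counts and 404 (1187) without the choroid-rich libraries. C1qa fell to 57.1 ± 12.6 CPM from 321 ± 70.6 CPM (-2.49 ± 0.19). Mapt rose (0.36 ± 0.1, adjusted p = 0.0321). Mapt lost its call without any one of CKO 1, T 2 or 4, TCKO 2 or 5 (0.0503 to 0.107). Prnp did not pass (0.21 ± 0.13, adjusted p = 0.287). Over all genes, 14.8% had libraries that did not overlap, where chance gives 2.86%. Mitochondrial genes took 8.6 ± 0.35% of reads in T and 7.72 ± 0.17% in TCKO (n = 4 each), where the highest TCKO library (7.93%) was below the lowest T library (8.07%). With mitochondrial genes left out, an alternative chosen after seeing the data, 2294 genes changed.

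All 21 interferon-stimulated genes fell (21 adjusted over the list alone), including Ifit2 (-2.06 ± 0.18), Rsad2 (-3.13 ± 0.33) and Oas1a (-3.69 ± 0.38). The interferon-stimulated list had a median log2 fold change of -3.28, with a camera adjusted p = 5.36e-31 and an adjusted p = 0.0224 with an estimated correlation. The chemokine genes Cxcl10 (-5.05 ± 0.74) and Cxcl13 (-6.02 ± 0.88) and the interferon-inducible Ifi211 (-5.21 ± 0.59) were among the largest falls. Of disease-associated microglia genes, 0 of 24 rose, 23 fell and 1 did not pass (0 and 23 adjusted over the list alone), with Axl (-1.42 ± 0.14), Ctsl (-1.2 ± 0.14) and Cd63 (-1.89 ± 0.22). The disease-associated microglia list had a median log2 fold change of -1.97, with a camera adjusted p = 8.28e-29 and an adjusted p = 0.0224 with an estimated correlation. In the homeostatic microglia list 1 of 16 rose, 10 fell and 5 did not pass (1 and 11 adjusted over the list alone), including Csf1r (-1.06 ± 0.15). The homeostatic microglia list had a median log2 fold change of -0.72, with a camera adjusted p = 5.29e-08 and an adjusted p = 0.0723 with an estimated correlation. All 18 complement and antigen presentation genes fell (18 adjusted over the list alone), with C1qb (-2.06 ± 0.22) and C1qc (-2.13 ± 0.2). The complement and antigen presentation list had a median log2 fold change of -2.06, with a camera adjusted p = 5.49e-28 and an adjusted p = 0.0224 with an estimated correlation. Of cytokines and NF-kB targets, 0 of 16 rose, 9 fell and 7 did not pass (1 and 11 adjusted over the list alone), including Ccl2 (-4.02 ± 0.45), Icam1 (-2.43 ± 0.27) and Ccl12 (-4.03 ± 0.53). The cytokines and NF-kB targets list had a median log2 fold change of -1.78, with a camera adjusted p = 6.9e-11 and an adjusted p = 0.00386 with an estimated correlation. Igkc, an immunoglobulin light chain gene, fell by 7.32 ± 1.51 on the log2 scale, and 163 of its CPM in T were in replicate 3 alone.

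Of reactive astrocyte genes, 0 of 24 rose, 21 fell and 3 did not pass (0 and 22 adjusted over the list alone), with Gbp2 (-2.59 ± 0.3) and Vim (-2.79 ± 0.35). The reactive astrocytes list had a median log2 fold change of -2.04, with a camera adjusted p = 3.11e-22 and an adjusted p = 0.0224 with an estimated correlation. In the astrocyte identity list 0 of 14 rose, 6 fell and 8 did not pass (0 and 7 adjusted over the list alone), including Aqp4 (-1.63 ± 0.22) and Sox9 (-0.95 ± 0.16). The astrocyte identity list had a median log2 fold change of -0.37, with a camera adjusted p = 1.49e-05 and an adjusted p = 0.119 with an estimated correlation. Of lysosomal genes 0 of 14 rose, 13 fell and 1 did not pass (0 and 13 adjusted over the list alone), with Grn (-1.45 ± 0.14). The lysosome list had a median log2 fold change of -0.91, with a camera adjusted p = 3.06e-14 and an adjusted p = 0.0272 with an estimated correlation. Cholesterol synthesis and uptake genes rose: 20 of 24 rose, 0 fell and 4 did not pass (23 and 0 adjusted over the list alone), including Idi1 (1.04 ± 0.13), Hmgcs1 (1.14 ± 0.17) and Insig1 (0.73 ± 0.11). The cholesterol synthesis and uptake list had a median log2 fold change of 0.7, with a camera adjusted p = 8.55e-17 and an adjusted p = 0.0272 with an estimated correlation. Of LXR targets and sterol handling genes 1 of 20 rose, 8 fell and 11 did not pass (1 and 8 adjusted over the list alone), with Abca1 (-2.26 ± 0.25), Npc2 (-1.2 ± 0.14) and Clu (-0.86 ± 0.11). The LXR targets and sterol handling list had a median log2 fold change of -0.37, with a camera adjusted p = 0.000295 and an adjusted p = 0.149 with an estimated correlation. In the matrix list 1 of 16 rose, 6 fell and 9 did not pass (1 and 9 adjusted over the list alone): the brain proteoglycan gene Ncan (0.65 ± 0.12) rose and Mmp12 (-3.21 ± 0.57) fell. The matrix metalloproteinases and matrix list had a median log2 fold change of -0.73, with a camera adjusted p = 0.00088 and an adjusted p = 0.119 with an estimated correlation.

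Camera placed the excitatory neuron, hippocampal subfield and immediate early lists above the other genes, while most of their members did not pass and the inhibitory neuron list was not called. In the interaction, given below, camera called the immediate early list but not the excitatory neuron or hippocampal subfield list. TCKO replicate 3 stood below the other TCKO libraries in the excitatory score (-0.2 against 0.2 to 0.27) and the hippocampal score (-0.17 against 0.55 to 0.62). Of excitatory neuron and synapse genes 6 of 16 rose, 0 fell and 10 did not pass (11 and 0 adjusted over the list alone), with Gria2 (0.7 ± 0.15), Gria1 (0.69 ± 0.16) and Camk2a (0.74 ± 0.21). The excitatory neuron and synapse list had a median log2 fold change of 0.46, with a camera adjusted p = 4.03e-06 and an adjusted p = 0.11 with an estimated correlation. In the hippocampal subfield list 3 of 16 rose, 0 fell and 13 did not pass (3 and 0 adjusted over the list alone), including Wfs1 (1.04 ± 0.23), a marker of pyramidal neurons. The hippocampal subfield neurons list had a median log2 fold change of 0.53, with a camera adjusted p = 0.00461 and an adjusted p = 0.21 with an estimated correlation. Of immediate early genes 5 of 14 rose, 0 fell and 9 did not pass (6 and 0 adjusted over the list alone), with Egr3 (0.99 ± 0.16), Egr1 (1.13 ± 0.28) and Nr4a1 (1.32 ± 0.35). The immediate early genes list had a median log2 fold change of 0.71, with a camera adjusted p = 0.000115 and an adjusted p = 0.206 with an estimated correlation. In the injury and stress response list 1 of 11 rose, 4 fell and 6 did not pass (2 and 4 adjusted over the list alone), with Nupr1 (-2.26 ± 0.26) and Cdkn1a (-1.55 ± 0.31); the list was not called (adjusted p = 0.242). Camk2a lost its call without T 2 (0.0747) or T 3 (0.0844) or TCKO 2 (0.0813) or TCKO 5 (0.0715). Nr4a1 lost its call without T 3 (0.0615) or T 4 (0.0611).

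Markers of other cells fell beside the microglial groups. Of T cell genes 0 of 13 rose, 10 fell and 3 did not pass (0 and 12 adjusted over the list alone), with Cd3d (-3.86 ± 0.67). The T cell list had a median log2 fold change of -2.7, with a camera adjusted p = 1.3e-09 and an adjusted p = 0.0272 with an estimated correlation. Border macrophage and monocyte genes included Ms4a7 (-3.95 ± 0.62), and 0 of 12 rose, 5 fell and 7 did not pass (0 and 8 adjusted over the list alone). The border macrophage and monocyte list had a median log2 fold change of -1.36, with a camera adjusted p = 9.63e-05 and an adjusted p = 0.0673 with an estimated correlation. Of meningeal and fibroblast genes 0 of 12 rose, 5 fell and 7 did not pass (0 and 6 adjusted over the list alone), with Fmod (-2.51 ± 0.53). The meninges and fibroblast list had a median log2 fold change of -1.24, with a camera adjusted p = 0.00171 and an adjusted p = 0.235 with an estimated correlation. In the endothelium and pericyte list 0 of 13 rose, 3 fell and 10 did not pass (0 and 4 adjusted over the list alone). The endothelium and pericyte list had a median log2 fold change of -0.29, with a camera adjusted p = 0.0185 and an adjusted p = 0.315 with an estimated correlation, and without T 2 the adjusted p was 0.118. Lists not called were inhibitory neuron (0 rose, 0 fell of 12, median 0.31, adjusted p = 0.242), oligodendrocyte and myelin (0 rose, 0 fell of 14, median -0.14, adjusted p = 0.684), oligodendrocyte precursor (0 rose, 0 fell of 10, median -0.32, adjusted p = 0.112), choroid plexus (0 rose, 0 fell of 15, median -2.11, adjusted p = 0.592), erythrocyte (0 rose, 0 fell of 5, median 1.27, adjusted p = 0.684) and thalamus and striatum (0 rose, 1 fell of 12, median 0.56, adjusted p = 0.492). On voom values, which camera tests, the median of the choroid plexus list was -0.34. The named rises Lzts1 (1.56 ± 0.35) and Lbhd2 (4.94 ± 1.36) were uneven in TCKO, where Lzts1 reached 787 CPM in replicate 3 against 271 to 328 in the others. Lbhd2 lost its call without T 2 (0.0829) or T 3 (0.0628) or T 4 (0.0522) or TCKO 3 (0.0611). The count of changed genes was 1354 from the 8 compared libraries alone, 1294 without T replicate 2, 1467 without TCKO replicate 5 and 1591 without the choroid-rich libraries. The oligodendrocyte precursor list gained a call without T 4 or T 5 or TCKO 3 (adjusted p from 0.0332 to 0.0428).

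**Figure D2:**
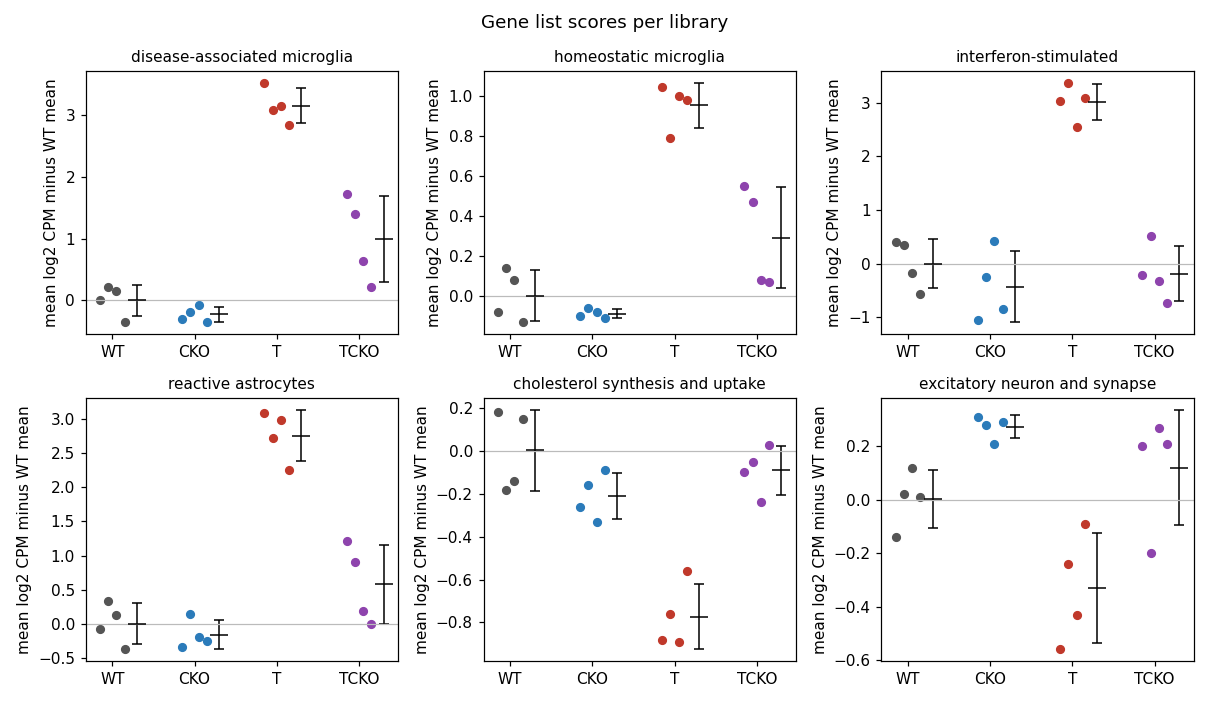
Score of 6 gene lists (y axes, mean log2 CPM of the list minus the WT mean) in each library (points) of the 4 groups (x axis), with the group mean and SD (black, n = 4). The interferon-stimulated score averaged 3.01 in T and -0.19 in TCKO, and the disease-associated microglia scores of the TCKO libraries were 1.73, 1.4, 0.63 and 0.22.

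The scores show the spread between libraries. The disease-associated microglia score was 3.15 ± 0.28 in T and 0.99 ± 0.7 in TCKO (n = 4 each), and all 4 T libraries were above all 4 TCKO libraries. The cholesterol score was -0.77 ± 0.15 in T and -0.09 ± 0.11 in TCKO. Both differences had an exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and an adjusted p = 0.0476 over the 25 lists. By the same score test the excitatory neuron (adjusted p = 0.0893), hippocampal subfield (adjusted p = 0.119) and endothelial (adjusted p = 0.15) lists, called by camera, did not pass. In TCKO against CKO no list passed the score test (lowest adjusted p = 0.119, for lists at the same smallest exact p). For T against WT the same exact p gave an adjusted p = 0.051. As the exact p cannot be smaller, a list can pass only where many of the 25 lists reach that value together. The adjusted p of a list at that value therefore depends on the other lists and does not judge the list alone.

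The comparison of CKO with WT asks what loss of Ch25h changes without the transgene. Genes called by edgeR were 2 of 18565, Ch25h (-4.53 ± 0.64, adjusted p = 0.0192) and Golga7b (-1.73 ± 0.24, adjusted p = 0.0192), which fell from 173 ± 22.2 CPM to 52 ± 13.5 CPM and also lies on chromosome 19. No member of the 25 lists rose or fell over all genes tested. Adjusted over the list alone, Pdgfra (-0.41 ± 0.12), Lum (-1.32 ± 0.37) and 2 T cell genes fell. By lists, camera placed 9 away from the other genes, and none of the 9 was called with an estimated correlation. At an unadjusted p under 0.05 there were 2098 genes, DESeq2 called 113 and limma voom 1. Over all genes, 8.94% had libraries that did not overlap between CKO and WT, where chance gives 2.86%. Genes are not independent, so this share does not count changed genes.

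Lists below the other genes were cholesterol synthesis and uptake (median -0.24, adjusted p = 6.17e-05, adjusted p = 0.713 with an estimated correlation), lysosome (median -0.17, adjusted p = 0.00331, adjusted p = 0.825 with an estimated correlation), interferon-stimulated (median -0.34, adjusted p = 0.00408, adjusted p = 0.825 with an estimated correlation), astrocyte identity (median -0.2, adjusted p = 0.0175, adjusted p = 0.825 with an estimated correlation), complement and antigen presentation (median -0.24, adjusted p = 0.0273, adjusted p = 0.825 with an estimated correlation), meninges and fibroblast (median -0.87, adjusted p = 6.17e-05, adjusted p = 0.635 with an estimated correlation) and choroid plexus (median -3.19, adjusted p = 0.0157, adjusted p = 0.825 with an estimated correlation). Lists above them were excitatory neuron and synapse (median 0.21, adjusted p = 6.17e-05, adjusted p = 0.635 with an estimated correlation) and hippocampal subfield neurons (median 0.27, adjusted p = 0.00192, adjusted p = 0.635 with an estimated correlation). Single libraries ended the calls of the choroid plexus list (0.581 without WT 1, 0.0567 without CKO 5), the interferon list (0.0585 without WT 2, 0.109 without CKO 1, 0.0624 without CKO 5) and the complement list (0.331 without WT 2, 0.122 without WT 4, 0.111 without CKO 1, 0.11 without CKO 5). The astrocyte identity call ended without WT 2 (0.0656), CKO 1 (0.153) or CKO 4 (0.0538). Ch25h lost its call without any one of WT 5, CKO 1, 2, 4 or 5 (0.0546 to 0.171). Golga7b lost its call without WT 5 (0.0713) or CKO 1 (0.132) or CKO 4 (0.0546) or CKO 5 (0.119). The count of calls was 7 without WT replicate 1, 1 without CKO replicate 2 and 0 without WT replicate 5 or CKO replicate 1, 4 or 5, and it was 8 without the choroid-rich libraries. The border macrophage and monocyte list gained a call without CKO 2 or CKO 4 (adjusted p from 0.039 to 0.0447). The disease-associated microglia list gained a call without WT 5 or CKO 4 or TCKO 2 or TCKO 5 (adjusted p from 0.0158 to 0.04). The immediate early genes list gained a call without WT 4 or CKO 4 (adjusted p from 0.0202 to 0.0313). The oligodendrocyte and myelin list gained a call without WT 5 (adjusted p = 0.00766).

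The comparison of TCKO with CKO asks what the transgene changes where Ch25h is absent. Camera placed microglial and complement lists above the other genes, but most of their members did not pass and none of these lists was called with an estimated correlation. Fry called 6 of the 25 lists, among them disease-associated microglia (fry adjusted p = 0.0483), homeostatic microglia (0.0321) and complement and antigen presentation (0.0321). No member of the interferon-stimulated list passed. Of 18565 genes 100 changed (65 higher, 35 lower), and 10.3% of all genes had libraries that did not overlap, where chance gives 2.86%. Mapt rose by 1.4 ± 0.11. Of disease-associated microglia genes 5 of 24 rose, 0 fell and 19 did not pass (18 and 0 adjusted over the list alone), with Clec7a (5.04 ± 0.82), Ccl4 (3.13 ± 0.58) and Cst7 (4.9 ± 0.92). The disease-associated microglia list had a median log2 fold change of 0.98, with a camera adjusted p = 4.45e-10 and an adjusted p = 0.228 with an estimated correlation. Of complement and antigen presentation genes 5 of 18 rose, 0 fell and 13 did not pass (16 and 0 adjusted over the list alone), with C1qa (1.26 ± 0.19), C1qc (1.17 ± 0.2) and C4b (2.09 ± 0.38). The complement and antigen presentation list had a median log2 fold change of 1.04, with a camera adjusted p = 7.08e-12 and an adjusted p = 0.226 with an estimated correlation. In the reactive astrocyte list 2 of 24 rose, 0 fell and 22 did not pass (7 and 0 adjusted over the list alone), with Gfap (1.81 ± 0.32). The reactive astrocytes list had a median log2 fold change of 0.73, with a camera adjusted p = 1.21e-05 and an adjusted p = 0.39 with an estimated correlation. In the lysosome list 1 of 14 rose, 0 fell and 13 did not pass (8 and 0 adjusted over the list alone), with Gusb (0.78 ± 0.14). The lysosome list had a median log2 fold change of 0.46, with a camera adjusted p = 7.18e-08 and an adjusted p = 0.226 with an estimated correlation. Of interferon-stimulated genes 0 of 21 rose, 0 fell and 21 did not pass (0 and 0 adjusted over the list alone). The interferon-stimulated list had a median log2 fold change of 0.25, with a camera adjusted p = 0.0829 and an adjusted p = 0.712 with an estimated correlation.

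Gbp2b was read 240 times in TCKO and 0 times in CKO, at least 67.3-fold higher, and Mmp12 was read 79 times against 1, a ratio of 66.5 (95% counting interval 11.6 to 2660). The microglial receptor gene Slamf9 (2.43 ± 0.34) rose, and among falls were Prdm15 (-1.03 ± 0.18) and Per2 (-0.87 ± 0.17). Further lists called were homeostatic microglia (1 rose and 0 fell of 16, median 0.44, adjusted p = 5.91e-07, adjusted p = 0.226 with an estimated correlation), cytokines and NF-kB targets (0 rose and 0 fell of 16, median 0.51, adjusted p = 0.0047, adjusted p = 0.226 with an estimated correlation), astrocyte identity (0 rose and 0 fell of 14, median 0.2, adjusted p = 0.0047, adjusted p = 0.502 with an estimated correlation), LXR targets and sterol handling (0 rose and 0 fell of 20, median 0.36, adjusted p = 2.88e-05, adjusted p = 0.226 with an estimated correlation), oligodendrocyte and myelin (0 rose and 0 fell of 14, median 1.0, adjusted p = 7.8e-09, adjusted p = 0.333 with an estimated correlation), immediate early genes (0 rose and 0 fell of 14, median 0.74, adjusted p = 0.0038, adjusted p = 0.518 with an estimated correlation) and, below the other genes, excitatory neuron and synapse (0 rose and 0 fell of 16, median -0.11, adjusted p = 0.0349, adjusted p = 0.537 with an estimated correlation). The last call ended without CKO 1 (0.0591), CKO 5 (0.0923) or TCKO 3 (0.513). Adjusted over the list alone, 13 of 14 oligodendrocyte and myelin, 9 of 16 homeostatic microglia and 8 of 20 LXR and sterol handling genes rose. So did 5 of 16 cytokine and NF-kB, 4 of 14 immediate early, 1 of 14 astrocyte identity and 0 of 16 excitatory neuron genes. Cholesterol synthesis genes did not pass (median 0.10, adjusted p = 0.055). Of 25 named genes called, 20 lost the call when some library was left out. Clec7a lost its call without CKO 1 (0.0799) or CKO 2 (0.0582) or CKO 4 (0.0603). Ccl4 lost its call without any one of CKO 1, 2, 4 or 5, TCKO 2 or 3 (0.0566 to 0.104). Cst7 lost its call without any one of CKO 1, 2, 4 or 5, TCKO 3 (0.0603 to 0.104). C1qc lost its call without CKO 1 (0.0953) or CKO 2 (0.0582) or CKO 4 (0.0847) or TCKO 3 (0.0683). C4b lost its call without any one of CKO 1, 2, 4 or 5, TCKO 2 or 3 (0.0562 to 0.0968). Gfap lost its call without any one of CKO 1, 2, 4 or 5, TCKO 3 (0.0583 to 0.0953). Gusb lost its call without any one of CKO 1, 2 or 4, TCKO 2 or 3 (0.051 to 0.0953). Mmp12 lost its call without any one of CKO 1, 2, 4 or 5, TCKO 2 or 3 (0.051 to 0.101). Prdm15 lost its call without CKO 1 (0.0721) or CKO 2 (0.0582) or CKO 4 (0.082) or TCKO 3 (0.0683). Per2 lost its call without any one of CKO 1, 2, 4 or 5, TCKO 2 or 3 (0.0759 to 0.102). The count of changed genes was 13 without CKO replicate 1, 12 without CKO 2, 11 without CKO 4, 51 without CKO 5, 55 without TCKO 2, 16 without TCKO 3, 266 without TCKO 4 and 207 without TCKO 5. By other tools it was 811 (DESeq2) and 59 (limma voom), and it was 301 from the 8 libraries alone and 252 without a filter on low counts. The T cell list gained a call without CKO 4 or TCKO 4 or TCKO 5 (adjusted p from 0.00966 to 0.0498). The cholesterol synthesis and uptake list gained a call without CKO 2 or CKO 5 or T 3 or TCKO 4 (adjusted p from 0.00497 to 0.0423). The erythrocyte list gained a call without WT 2 or WT 4 or CKO 4 or T 3 or T 4 or T 5 or TCKO 2 or TCKO 5 (adjusted p from 0.00342 to 0.0452). With all libraries camera placed it below the other genes, although its edgeR median was 0.09. The interferon-stimulated list gained a call without CKO 2 or CKO 4 or TCKO 4 or TCKO 5 (adjusted p from 0.00461 to 0.0498). The meninges and fibroblast list gained a call without CKO 1 (adjusted p = 0.00109). The oligodendrocyte precursor list gained a call without WT 2 or WT 4 or WT 5 or CKO 4 or CKO 5 or T 2 or T 5 or TCKO 5 (adjusted p from 0.00966 to 0.0451).

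The interaction tests whether the transgene effect differs with the Ch25h genotype, as the change in TCKO against CKO minus the change in T against WT. By camera the transgene effect on the interferon, complement and microglial lists was smaller where Ch25h was absent, but none of these was called with an estimated correlation. Fry called 9 of the 25 lists, among them interferon-stimulated (fry adjusted p = 0.00134) and complement and antigen presentation (0.00134). Disease-associated microglia (fry adjusted p = 0.0021) and homeostatic microglia (0.0115) were also called by fry. Part of the members of these lists did not pass, and other groupings of the libraries, given below, did not decide on chance. The cholesterol synthesis list, below the other genes in T against WT (median -0.76), did not pass in TCKO against CKO (median 0.10). Of 18565 genes 584 differed (129 higher, 455 lower). Of interferon-stimulated genes 0 of 21 were higher, 19 were lower and 2 did not pass (0 and 20 adjusted over the list alone), with Ifit2 (-1.84 ± 0.25) and Isg15 (-4.13 ± 0.59) and Oasl1 outside the list at -4.64 ± 0.96. The interferon-stimulated list had a median log2 fold change of -2.74, with a camera adjusted p = 7.99e-23 and an adjusted p = 0.0552 with an estimated correlation. Mx1 (-7.42 ± 1.16) rests on 3 reads in TCKO. Of complement and antigen presentation genes 0 of 18 were higher, 11 were lower and 7 did not pass (0 and 18 adjusted over the list alone), with C1qa (-2.45 ± 0.26), C1qb (-1.97 ± 0.3) and C1qc (-2.19 ± 0.28). The complement and antigen presentation list had a median log2 fold change of -2.01, with a camera adjusted p = 3.22e-20 and an adjusted p = 0.0552 with an estimated correlation. Of disease-associated microglia genes 0 of 24 were higher, 13 were lower and 11 did not pass (0 and 19 adjusted over the list alone), with Axl (-1.32 ± 0.2) and Trem2 (-1.93 ± 0.35). The disease-associated microglia list had a median log2 fold change of -1.79, with a camera adjusted p = 6.37e-19 and an adjusted p = 0.0552 with an estimated correlation. Of cholesterol synthesis and uptake genes 16 of 24 were higher, 0 were lower and 8 did not pass (22 and 0 adjusted over the list alone), with Idi1 (1.22 ± 0.19) and Insig1 (0.93 ± 0.16). The cholesterol synthesis and uptake list had a median log2 fold change of 0.93, with a camera adjusted p = 7.99e-23 and an adjusted p = 0.0371 with an estimated correlation.

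In the reactive astrocyte list 0 of 24 were higher, 10 were lower and 14 did not pass (0 and 18 adjusted over the list alone), with Gbp2 (-2.47 ± 0.42) and Stat3 (-1.12 ± 0.19). The reactive astrocytes list had a median log2 fold change of -1.9, with a camera adjusted p = 1.25e-15 and an adjusted p = 0.0552 with an estimated correlation. For cytokines and NF-kB targets 0 of 16 were higher, 5 were lower and 11 did not pass (0 and 9 adjusted over the list alone), with Icam1 (-2.05 ± 0.39). The cytokines and NF-kB targets list had a median log2 fold change of -1.52, with a camera adjusted p = 2.75e-06 and an adjusted p = 0.0371 with an estimated correlation. Single genes included Abca1 (-2.28 ± 0.34), Scd1 (1.23 ± 0.26), Grn (-1.27 ± 0.19), Ctsz (-1.67 ± 0.3), Nupr1 (-2.14 ± 0.36), Aqp4 (-1.43 ± 0.3) and Csf1r (-1.11 ± 0.21). Further lists called were homeostatic microglia (0 higher and 5 lower of 16, median -0.58, adjusted p = 2.49e-06, adjusted p = 0.153 with an estimated correlation), lysosome (0 higher and 6 lower of 14, median -0.7, adjusted p = 3.47e-09, adjusted p = 0.101 with an estimated correlation), astrocyte identity (0 higher and 2 lower of 14, median -0.36, adjusted p = 0.00819, adjusted p = 0.401 with an estimated correlation), LXR targets and sterol handling (1 higher and 4 lower of 20, median -0.41, adjusted p = 0.00307, adjusted p = 0.294 with an estimated correlation), matrix metalloproteinases and matrix (0 higher and 1 lower of 16, median -0.54, adjusted p = 0.0104, adjusted p = 0.289 with an estimated correlation), T cell (0 higher and 0 lower of 13, median -1.44, adjusted p = 0.000239, adjusted p = 0.187 with an estimated correlation) and border macrophage and monocyte (0 higher and 0 lower of 12, median -1.17, adjusted p = 0.0229, adjusted p = 0.294 with an estimated correlation). Immediate early genes (0 higher and 0 lower of 14, median 0.43, adjusted p = 0.0104, adjusted p = 0.428 with an estimated correlation) and endothelium and pericyte (0 higher and 1 lower of 13, median -0.34, adjusted p = 0.0429, adjusted p = 0.428 with an estimated correlation) were also called. Leaving out single libraries ended the calls of the border macrophage list (0.063 to 0.078 without CKO 2 or 4, T 4 or TCKO 4), the immediate early list (0.0538 without WT 4, 0.0819 without T 4) and the endothelial list (0.0615 to 0.151 without WT 1 or 4, CKO 2 or 5, T 2 or 4 or TCKO 2 or 4).

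Genes with the largest positive interaction were uneven between libraries. Sln (6.45 ± 1.35) was at 24.6 CPM in WT replicate 2, 21.3 in TCKO replicate 3 and 31.3 in TCKO replicate 4, and at most 5.47 elsewhere. Avpr1a (8.6 ± 1.84) and Lbhd2 (8.44 ± 1.9) peaked in TCKO replicate 3, at 8.71 and 42.6 CPM. Lbhd2 lost its call without any one of WT 2, CKO 1, 2, 4 or 5, T 2 or 3 (0.0509 to 0.0603). With the replicate number as a block, the calls of Sln (blocked adjusted p = 0.0596) and Lbhd2 (0.0588) ended. Ms4a7 (-3.08, adjusted p = 0.0702) gained a call with the block (blocked adjusted p = 0.0249). The thalamus and striatum scores of WT replicate 2, TCKO replicate 3 and TCKO replicate 4 were 0.99, 1.47 and 0.86. T replicate 2, with Sln at most 5.47 CPM, scored 0.77. The count of genes was 334 without WT replicate 5, 375 without CKO 1, 349 without CKO 2, 308 without CKO 4, 298 without T 2, 334 without T 3, 1266 without T 5 and 351 without TCKO 5. DESeq2 gave 1271, and 378 differed without the choroid-rich libraries. The choroid plexus list gained a call without WT 5 or T 4 (adjusted p from 0.00325 to 0.0464). With all libraries the excitatory neuron and synapse list was not called in the interaction (median 0.15, camera adjusted p = 0.0983). Nor was the hippocampal subfield neurons list (median 0.28, camera adjusted p = 0.623). The excitatory neuron and synapse list gained a call without WT 1 or T 3 or T 5 or TCKO 3 (adjusted p from 0.00706 to 0.0398).

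**Figure D3:**
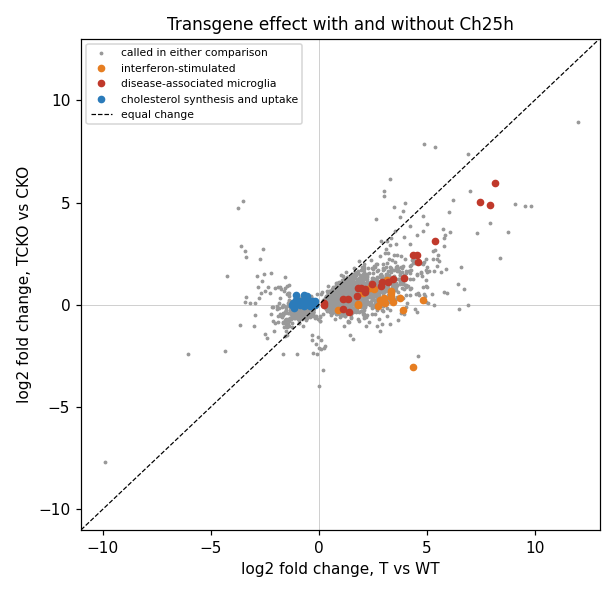
Log2 fold change of T against WT (x axis) and of TCKO against CKO (y axis) for genes called in either comparison (grey points), with 3 gene lists in colour and the line of equal change dashed. The slope across the called genes was 0.33.

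Across the 4519 genes called in either comparison, the transgene effects with and without Ch25h had a Pearson correlation of 0.66 (jackknife SE 0.17) and a slope of 0.33 (SE 0.10), and 81.5% had the same sign. Over all 18565 genes tested the correlation was 0.39, the slope 0.29 and the share with the same sign 65.2%. These 2 comparisons share no library, and genes are not independent replicates. Genes higher in T than in WT and lower in TCKO than in T numbered 1310, where independent lists would share 194.6; genes lower and then higher numbered 648, where 99.7 would be shared. The 2 comparisons share the T libraries, so the T libraries were split, with genes called against WT in one part and the TCKO difference taken from the other. Over 6 such splits the median share of called genes with the opposite sign in TCKO against T was 95.5% (83.7 to 96.8). Genes that rose and then fell numbered 828 (654 to 983) in the median of these splits, and genes that fell and then rose 106.5 (35 to 194); these splits also use fewer libraries. The unsplit share was 97.1% of the genes called by edgeR, and simulated unchanged groups gave 77.2% (76 to 78.7). The simulated share is over the 4490 genes with the largest differences, taken without a test, and genes were simulated independently. The 2 shares are therefore not over like sets of genes. The covariance of the fold changes was -0.47, against -0.0823 in the simulation.

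Because a targeted locus can carry flanking sequence of another strain, genes within 5 Mb of Ch25h were counted. In TCKO against T, 12 of 62 tested genes near Ch25h changed, among them Ifit1, Ifit2 and Ifit3 (19.4% against 12.8% elsewhere, Fisher's exact test, two-sided, p = 0.128). Within 2 Mb 7 of 26 changed (Fisher's exact p = 0.0693) and within 10 Mb 30 of 150 (Fisher's exact p = 0.0136). Each of these counts includes Ch25h, the targeted gene itself. With Ch25h left out, after seeing the data, 11 of 61 changed within 5 Mb (Fisher's exact p = 0.247). The counts were then 6 of 25 within 2 Mb (Fisher's exact p = 0.124) and 29 of 149 within 10 Mb (Fisher's exact p = 0.0194). In the interaction 5 of 62 genes within 5 Mb differed (Fisher's exact p = 0.0452), and the same 5, Fas, Ifit1, Ifit2, Ifit3 and Ifit3b, were 5 of 26 within 2 Mb (odds ratio 7.38, Fisher's exact p = 0.00115). These 5 genes were also called in T against WT, where the Ch25h genotype does not differ, and not in CKO against WT, where it does. Fisher's test treats genes as independent, but Ifit1, Ifit2 and Ifit3 belong to the interferon-stimulated list, which moved together. The p-values therefore do not decide on flanking sequence. In CKO against WT, 1 of 62 changed (Fisher's exact p = 0.00667), and that gene is Ch25h itself; without it the count was 0 of 61 (p = 1), a comparison added after seeing the data. Golga7b lies within 10 Mb, where 2 of 150 changed, Ch25h counted (Fisher's exact p = 6.49e-05), and 1 of 149 with Ch25h left out (Fisher's exact p = 0.00803).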

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

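The tests weighed here, except the splits of the libraries that were planned (all but the regrouping with the transgene status kept), were chosen after the result was seen. A library stood far from the other 3 of its group, by the ratio of its gap to the group's range, in 38 of 456 groups tested (8.33%), where chance gives about 5%. In CKO replicate 1, Csf1r was 68.5 CPM against 72.2 to 72.6. In CKO replicate 2, Nr4a1 was 145 CPM against 50 to 65.3, the lysosome score was -0.13 against -0.22 to -0.21. In CKO replicate 4, Ccl2 was 0.325 CPM against 0.11 to 0.129, Ccl4 was 0.781 CPM against 0.328 to 0.388, Cxcl10 was 3.32 CPM against 0.205 to 0.517. There too, Igkc was 0.586 CPM against 0 to 0.0862, Mmp12 was 0.0651 CPM against 0 to 0. In T replicate 2, Axl was 100 CPM against 83.8 to 85.2, C1qa was 426 CPM against 270 to 296, C1qc was 281 CPM against 192 to 196. There too, Clec7a was 135 CPM against 86.4 to 94, Itgax was 39.8 CPM against 22 to 24.3. In T replicate 3, Cd3g was 3.81 CPM against 1.15 to 1.59, Cxcl13 was 29 CPM against 7.1 to 8.47, Igkc was 163 CPM against 0.656 to 9.34. There too, the library total was 26.25 M reads against 31.62 to 32.3, the mitochondrial share was 8.07% against 8.73 to 8.81. In T replicate 5, Msmo1 was 92.9 CPM against 63 to 67.1, Sc5d was 87.8 CPM against 79.2 to 80.3. In TCKO replicate 3, Avpr1a was 8.71 CPM against 0.156 to 1.52, Lzts1 was 787 CPM against 271 to 328, Mx1 was 0.0951 CPM against 0 to 0. There too, Scd1 was 176 CPM against 125 to 132, the excitatory neuron and synapse score was -0.2 against 0.2 to 0.27, the hippocampal subfield neurons score was -0.17 against 0.55 to 0.62. There too, the oligodendrocyte and myelin score was 1.18 against 0.91 to 0.94. In TCKO replicate 4, Olig2 was 7.19 CPM against 2.54 to 3.2, Sc5d was 101 CPM against 121 to 122. In TCKO replicate 5, C1qa was 38.2 CPM against 62.8 to 64. In WT replicate 1, Cxcl10 was 2.94 CPM against 0.712 to 0.812, Oasl1 was 0.678 CPM against 0.0297 to 0.108. In WT replicate 2, Avpr1a was 4.18 CPM against 0.212 to 0.324, C4b was 50.8 CPM against 27.1 to 30.9, Lbhd2 was 25.5 CPM against 0.177 to 2.84. There too, Sln was 24.6 CPM against 2.26 to 5.47. In WT replicate 5, Cd3d was 0 CPM against 0.108 to 0.129, Ctsl was 103 CPM against 120 to 122.

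The transgene effect differed between the Ch25h genotypes by the interaction test for these named genes, with the log2 difference in parentheses: Abca1 (-2.28), Aqp4 (-1.43), Avpr1a (8.6), Axl (-1.32), C1qa (-2.45), C1qb (-1.97), C1qc (-2.19), Ccl12 (-3.45), Csf1r (-1.11), Ctsz (-1.67), Cxcl10 (-4.58), Gbp2 (-2.47), Grn (-1.27), Icam1 (-2.05), Idi1 (1.22), Ifi211 (-4.47), Ifit2 (-1.84), Insig1 (0.93), Isg15 (-4.13), Lbhd2 (8.44), Mx1 (-7.42), Npc2 (-0.86), Nupr1 (-2.14), Oasl1 (-4.64), Scd1 (1.23), Sln (6.45), Stat3 (-1.12), Tph1 (3.58), Trem2 (-1.93). It also differed for these lists by camera, with the median difference: disease-associated microglia (-1.79), homeostatic microglia (-0.58), interferon-stimulated (-2.74), complement and antigen presentation (-2.01), cytokines and NF-kB targets (-1.52), reactive astrocytes (-1.9), astrocyte identity (-0.36), cholesterol synthesis and uptake (0.93), LXR targets and sterol handling (-0.41), lysosome (-0.7), matrix metalloproteinases and matrix (-0.54), immediate early genes (0.43), endothelium and pericyte (-0.34), T cell (-1.44), border macrophage and monocyte (-1.17). With an estimated correlation 2 of these 15 lists were called, cholesterol synthesis and uptake and cytokines and NF-kB targets (adjusted p = 0.0371 each). The value of Mx1 rests on 3 reads in TCKO. Of 46 named genes called, 18 lost the call when some library was left out. Tph1 lost its call without any one of WT 2 or 4, CKO 1, 2, 4 or 5, T 3, 4 or 5, TCKO 2, 3 or 5 (0.0508 to 0.101). Npc2 lost its call without any one of WT 5, CKO 2, 4 or 5, T 2 or 4, TCKO 5 (0.0509 to 0.0664). Cxcl10 lost its call without WT 5 (0.0546) or CKO 4 (0.126) or T 2 (0.0564) or T 3 (0.0508). Ifi211 lost its call without CKO 4 (0.0661). Ccl12 lost its call without CKO 4 (0.0624). With the replicate number as a block, the calls of Sln (blocked adjusted p = 0.0596), Lbhd2 (0.0588) and Tph1 (0.0861) ended.

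The fall of response genes in TCKO against T was weighed against technical causes. With every library thinned to the lowest total 2239 genes changed, against 2388 at full depth, which argues against depth. Mapt was higher in TCKO by 0.36, a call lost without some single libraries, so its total reads were not lower there. These reads can mix mouse and human tau, and the excitatory neuron score was also higher in TCKO (0.12) than in T (-0.33). Less transgene RNA per neuron therefore stays open. The 18 interferon genes on chromosomes other than 19 had a median of -3.26, which argues against an effect of flanking sequence on neighbours alone. The disease-associated score less the homeostatic score was 2.2 ± 0.26 in T and 0.7 ± 0.45 in TCKO, a difference of -1.5 (exact permutation p = 0.0286, n = 4). An even loss of unchanged microglia would lower both scores alike only if both lists were read from microglia alone. In bulk tissue this was not tested, so the difference does not decide on such a loss. A biological effect of Ch25h loss may remain, but fewer disease-associated cells, a changed mix of cells or an untested difference in background could give the same values.

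In CKO against WT few genes were called, and low depth of the CKO libraries is a candidate cause. Thinned to equal depth T against WT gave 4231 genes, but its changes are larger, so that count does not decide. In counts simulated at these library sizes, 68.7% of 2-fold and 98.5% of 4-fold changes were recovered for CKO against WT. For T against WT the shares were 61.2% and 89.4%. These values argue against depth hiding most changes of 2-fold or more in genes of at least 1 CPM. For smaller changes and lower genes depth stays open. Choroid plexus tissue in WT replicate 1 could also widen the spread, but without the choroid-rich libraries 8 genes were called. A small effect of Ch25h loss in this tissue stays open, as changes of 1.5-fold were mostly missed on simulated data.

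Other groupings of the same libraries were counted for each comparison. For T against WT 1 of 35 splits, the real one, called as many as 4490 genes, and the highest other called 4. For TCKO against T it was also 1 of 35, with 2388 genes and 1414 in the highest other, which exchanged T replicate 5 and TCKO replicate 4. As 1 of 35 is the smallest share that these splits allow, neither count alone excludes chance. For CKO against WT 2 of 35 splits reached the real count of 2, with 2 in the highest other, and chance cannot be excluded. For TCKO against CKO 2 of 35 reached 100 genes, the highest other calling 174 with CKO replicate 5 and TCKO replicate 2 exchanged, and chance cannot be excluded. For the interaction 2 of 100 regroupings reached 584 genes, but they move the transgene effect itself; the highest other, with 1925, set 7 transgenic libraries against 7 of the others. With the transgene status kept and only the Ch25h genotype regrouped, 5 of 100 reached 584 genes, with 1434 in the highest other. Those others kept T and TCKO whole or exchanged T replicate 5 and TCKO replicate 4, so they retain the difference of TCKO from T, and neither set decides on chance for the interaction.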

How the results depend on the processing

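The added alternatives (thinning, length offset, choroid-rich libraries, mitochondrial genes and the neighbourhood without Ch25h) were chosen after the result was seen. Of 299 gene and comparison pairs under 8283 alternatives, 509 values lost the call and 0 reversed, and 0 of 2375 list alternatives reversed; 95 list or gene values changed sign where neither was called. Other scalings moved the median of all genes by at most 0.05 and no split of rises and falls by over 10 points. For T against WT (4490) the count was 2732 at a fold of at least 1.5 and 2696 without the choroid-rich libraries, and 2934 to 5128 leaving out 1 library. For CKO against WT (2) it was 113 with DESeq2, 1 with limma voom, 1 from the 8 libraries alone, 0 with the replicate block, 8 without the choroid-rich libraries, and 0 to 7 leaving out 1 library. For TCKO against T (2388) it was 1354 from the 8 libraries alone, 1571 at a fold of at least 1.5, 1591 without the choroid-rich libraries, and 1294 to 3278 leaving out 1 library. For TCKO against CKO (100) it was 252 without a filter, 811 with DESeq2, 59 with limma voom, 5 with the replicate block, 301 from the 8 libraries alone, and 11 to 266 leaving out 1 library. For the interaction (584) it was 1271 with DESeq2, 378 without the choroid-rich libraries, and 298 to 1266 leaving out 1 library. Lists called fell from 14 to 9, 9 to 0, 18 to 8, 11 to 0 and 15 to 2 with an estimated correlation. The correlation of transgene effects was 0.39 over all genes tested. Near Ch25h, the 10 Mb window gave 30 genes in TCKO against T, Ch25h counted, past the threshold. In CKO against WT, leaving Ch25h out gave 0 genes within 5 Mb and 1 within 10 Mb. Fewer libraries or genes enter some of these by construction; otherwise the cause was not tested.

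With the replicate number as a block, T against WT gave 3411 genes, TCKO against T 2262 and the interaction 683. For T against WT 3257 of these genes were among the 4490, and of the genes and lists in the text the block changed no other call than those given beside that comparison. In the interaction, which contains WT, CKO and T, it ended the calls of Sln, Lbhd2 and Tph1, and Ms4a7 gained a call. In the remaining comparisons the libraries share only a number. Of same-numbered pairs, 2 of 4 were over 0.1 for WT and CKO. The counts were 1 of 4 for T and TCKO and 0 of 3 for CKO and TCKO. Not every library correlated best with its own number there, nor for WT and T, where 2 of 3 did. Depth limits the low genes: 3 counts correspond to 0.1991 CPM in CKO replicate 4 and 0.0873 in WT replicate 2.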

Other observations

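The test of genes near Gbp2b was set before its result was seen. Golga7b, on chromosome 19 at 42247574 to 42270348, was at 173 ± 22.2 CPM in WT, 52 ± 13.5 CPM in CKO, 102 ± 21.8 CPM in T and 64.1 ± 25.6 CPM in TCKO. In TCKO against T its log2 fold change was -0.68 ± 0.23 (adjusted p = 0.0663).

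Among tested genes, 4 had 0 reads in all 8 libraries without the transgene, and 2 of these were read in all 8 with it. Both lie on chromosome 3: Gbp2b at 142594847 to 142619179, with 2286 reads in T and 240 in TCKO, and 4930590L14Rik at 140951876 to 140953247, with 67 and 78. The other two, Apoc4 and Klrb1b, were read in all 4 T and in 3 TCKO libraries. In the opposite direction 1 gene had 0 reads in all 8 transgenic libraries. A candidate explanation is sequence linked to the transgene insertion; of 106 other genes within 10 Mb of Gbp2b, 0 were called in TCKO against CKO, an odds ratio of 0 (upper 95% limit 6.76, Fisher's exact p = 1). The odds ratio was on the side set beforehand against the explanation, but its interval reaches above 1, so few calls keep it open; the first run of this test had counted 4930590L14Rik, and the requirement on the interval was added after that value was seen.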
